A study of Mus musculus with 6 samples.

How the data were processed

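Poly(A) selection or depletion, strand and read length of the libraries are not given in the sources used here. Per the labels' protocols, RNA was harvested with Trizol from macrophages grown from bone marrow with M-CSF and then stimulated with IFN-γ and LPS, and libraries followed Illumina's standard procedure. The authors deposited 1 table of whole-number read counts per gene, with gene symbols in rows and 1 column for each of the 6 libraries, not normalized. Per the submitters' processing notes, reads were aligned with HISAT2 and the genome build was GRCm38; the version, the counting tool, the annotation and the strand setting are not given in the sources used here. Without a strand setting, reads of overlapping and antisense genes cannot be told apart, and the handling of reads that match several places decides the counts of multigene families.

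Each column was assigned by its name, which matches 1 library's title, and 0 columns of per-sample values were left unused. No row of the table failed to name a gene. Total counts were 17963645, 16838527 and 21658061 in WT replicates 1 to 3 and 18867799, 16925955 and 18446822 in Cd226-/- replicates 1 to 3, so that 1 count was worth 0.0452 to 0.0600 CPM. A count of 0 allows up to 3 counts in that library (0.136 to 0.180 CPM). Intervals, floors and tests on counts of single libraries cover counting error only. Within each genotype every pair of libraries differed by more than counting noise, so all 6 were kept as separate samples. Chi-square over degrees of freedom was 2.17 to 7.76 for genes with at least 20 counts in the pair. It was lowest for Cd226-/- replicates 2 and 3 (2.17), against 7.61 and 7.76 for replicate 1 with each of them. Pairs of WT libraries had 3.79 to 6.32. Cd226-/- replicates 2 and 3 were thus the most alike by this ratio, and the labels do not say whether they are independent samples.

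Counts were tested in R 4.3.3 with edgeR 4.0.16: genes were filtered with filterByExpr by genotype, scaled by TMM, and tested with the robust quasi-likelihood F-test, two-sided, with genotype as the only term, and p-values were adjusted by the method of Benjamini and Hochberg over 13215 genes. The biological coefficient of variation was 6.75%. Standard errors are the log2 fold change divided by the square root of F. CPM values use the TMM-scaled library sizes. Gene lists, 46 in all with 948 distinct members, were fixed before the data were examined; 947 members matched a row, 13 of them through an older or alternative symbol. The 44 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Gene positions come from a RefSeq table of the same build, which holds 94.8% of the tested symbols.

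The genes named were also chosen by a rule fixed beforehand: Cd226; the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between genotypes, without names of the Gm, Rik, pseudogene or accession type; up to 3 changed members, by p, of each list that was called or had at least 3 changed members; and Nos2, Tnf, Il6, Il1b, Il12b, Cd86, Arg1, Mrc1 and Il10 whatever their values. The rule gave 143 genes, part of which are described. Other genes were named after their values were seen: H2-Aa, Hmox1, Prdx5, Sod2, COX3, Alb, Xist and Ddx3y in the results, and those of the closing section. No overlap between 3 and 3 libraries arises by chance for 10% of genes and was seen for 44.3%.

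The alternatives were DESeq2 (1.42.0) size factors, scaling by library size alone, no filter, a filter at a mean of 5 CPM, DESeq2's Wald test, limma-voom, the replicate number as a block, each library left out in turn, a 2-fold minimum and an adjusted p under 0.01. Chosen after seeing the data were the fit with replicate 1 as the only Cd226-/- library and per-library offsets for GC content and transcript length (lowess span 0.3, 94.1% of tested genes with values, from GENCODE transcripts of the same build). With replicate 1 alone the spread comes from the WT libraries only, and the lone library is assumed to vary like them. Further gene lists, given in the closing section, were written after the data were seen. Among them, the second hepatocyte set was written without looking at its counts. Proportions of liver transcripts were compared with a permutation test.

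The steps were tested on simulated data for this comparison: 10 sets of counts for the 13215 genes, each with 200 genes changed. edgeR recovered 38.0% of genes changed 1.25-fold, 65.2% at 1.5-fold, 80.0% at 2-fold and 92.8% at 3-fold. Among genes with a mean of at least 50 counts these shares were 47.7%, 83.9%, 96.9% and 99.0%. Unchanged genes made up 8.06% of edgeR's calls, above the nominal 5%, and 7.27% for DESeq2 and 9.95% for limma-voom. The adjusted p-values here may therefore be slightly too small. Each set changed 200 genes, whereas 4086 were called in the real data, so these shares and recoveries may not carry over. With nothing planted 0 genes were called by edgeR in 1 such set. A planted list of 20 genes moved 1.3-fold, with means above 200 counts, was called by camera with both correlations and by fry. With the preset correlation 0 of 20 random lists were called, and for the other list tests this was not counted. Genes were simulated independently of each other, whereas estimated correlations in the real lists reached 0.66. The simulated sets therefore cannot show how the list tests behave where genes of a list vary together. A planted GC trend gave 2421 calls, and 3 with the offsets.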

Results

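RNA sequencing of bone marrow-derived macrophages from C57BL/6 mice aged 56 days was compared between wild-type animals (WT) and animals lacking Cd226, which encodes the activating adhesion receptor CD226 (DNAM-1). Marrow cells were grown for 7 days in M-CSF at 20 ng/ml, the cytokine that drives macrophage differentiation, and then stimulated for 24 h with IFN-γ at 20 ng/ml and LPS at 100 ng/ml, a treatment that yields M1-type macrophages. There were 3 libraries per genotype, all stimulated. The labels do not say whether the replicates came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical. Total counts per library ranged from 16838527 (WT replicate 2) to 21658061 (WT replicate 3), and from 16925955 to 18867799 in Cd226-/-. Of the 46095 genes in the table, 22604 had at least 1 count and 13215 were tested.

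The question the design poses is which genes differ between Cd226-/- and WT macrophages after the same M1 stimulus. Ly6c2, a monocyte antigen, rose 6.78-fold (30.2 ± 0.745 CPM in WT and 205 ± 12.2 CPM in Cd226-/- (SD, n = 3)), and the neutrophil-attracting chemokine Cxcl2 fell by 1.58 on the log2 scale. Of 21 glycolysis genes 13 rose and 1 fell, of 20 hypoxia response genes 15 rose and 2 fell, and of 21 oxidative stress response genes 3 rose and 16 fell. Each of these lists was called with a preset correlation and had adjusted p = 0.174 with an estimated correlation. Of 23 M1-associated genes 17 rose and 2 fell (adjusted p = 0.225 with an estimated correlation). The targeted gene, Cd226 (chromosome 18, 89176954 to 89272232, GRCm38) was barely detected in either genotype. It had 5, 17 and 23 counts in WT replicates 1 to 3 and 11, 10 and 8 counts in Cd226-/- replicates 1 to 3. The ratio of summed counts per total count was 0.671 (95% exact interval 0.406 to 1.09, counting error only), and the gene test did not separate the genotypes (log2 fold change -0.50 ± 0.50 (SE), adjusted p = 0.480). The counts therefore did not check the genotype labels, since a deletion of part of the gene can leave reads from the rest and the level was near the detection limit.

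At an adjusted p under 0.05 in edgeR's quasi-likelihood test, 4086 genes (30.9% of those tested) differed, 2130 higher and 1956 lower in Cd226-/-. Most changes were small: the median absolute log2 fold change among them was 0.41, and 571 changed at least 2-fold, 403 higher and 168 lower. The split depends on scaling, since 1773 were higher and 2764 lower when libraries were scaled by total count alone. In principal components of log2 CPM the first component (54.4% of variance) separated the genotypes. The second (15.5%) separated Cd226-/- replicate 1 from replicates 2 and 3. With replicate 1 as the only Cd226-/- library, an alternative chosen after seeing the data, 2957 genes differed, with the spread taken from the WT libraries only.

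Among genes with a mean of at least 5 CPM and no overlap between genotypes, names of the Gm, Rik, pseudogene or accession type left out, Ly6c2 had the largest rise (adjusted p = 7.55e-19). Cst7, encoding the protease inhibitor cystatin F, rose 5.57-fold (10.8 ± 0.904 CPM in WT and 60.5 ± 2.43 CPM in Cd226-/- (SD, n = 3)). Cxcl12, a chemokine of stromal cells, rose 4.82-fold, Asns, the asparagine synthetase, 4.30-fold, Tnfsf15, a TNF-family cytokine, 4.21-fold, and Retnla, an alternative-activation marker, 4.18-fold. The B-cell antigen gene Ms4a1 rose 3.99-fold, and the immunoglobulin kappa entries Igk and Igkv4-91 rose 5.04-fold and 3.71-fold. Slco4a1 rose 4.40-fold (adjusted p = 0.0221) but missed the threshold without WT replicate 1 (adjusted p = 0.0780), WT replicate 2 (0.0524) or WT replicate 3 (0.0667). Its adjusted p ranged from 7.76e-12 to 0.0780 over all alternatives. Ly6c2 and the immunoglobulin genes have near-identical relatives, so their own share of the counts is uncertain.

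The largest fall was that of Dmpk, a protein kinase gene (log2 fold change -2.42 ± 0.20 (SE); 11.1 ± 0.824 CPM in WT and 2.05 ± 0.737 CPM in Cd226-/- (SD, n = 3)). The neutrophil-attracting chemokines Cxcl5 and Cxcl2 fell, with log2 fold changes of -2.14 and -1.58, and Cxcl2 went from 353 ± 14.8 to 118 ± 8.78 CPM (SD, n = 3). Slc40a1, the iron exporter ferroportin, fell by 2.03 on the log2 scale. The other large falls had log2 fold changes of -1.89 for Ctgf, -1.88 for Cdkn2a, -1.77 for Mgst2, -1.75 for Cryab, -1.50 for Col12a1 and -1.49 for Cxcl14. All 6 had adjusted p at or below 2.89e-06, and their 3 Cd226-/- values lay below the 3 WT values.

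**Figure D1:**
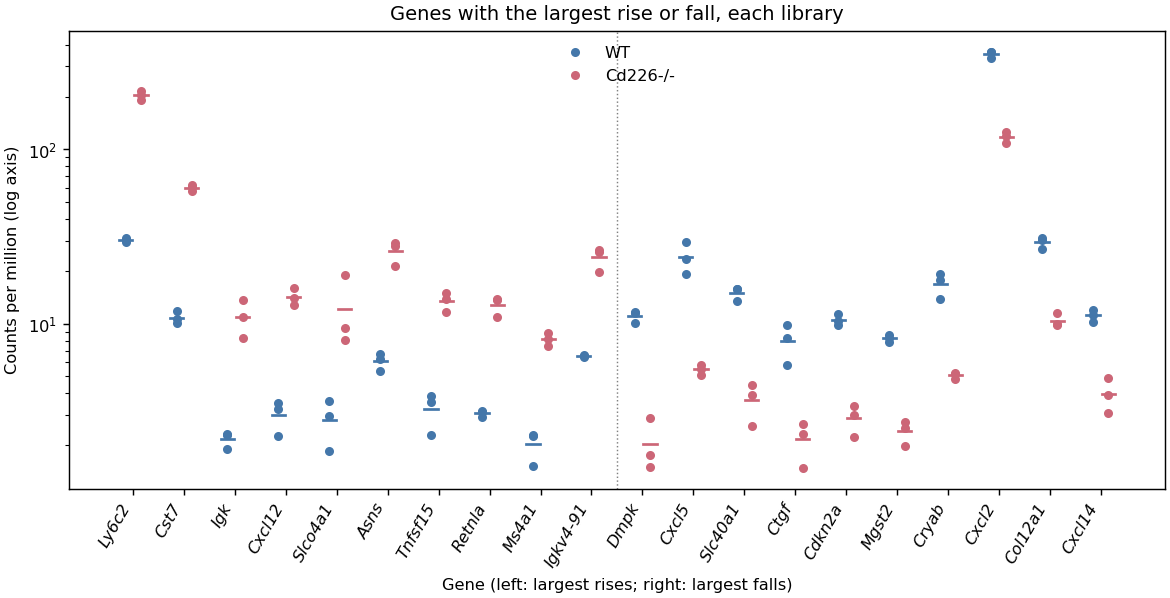
CPM (log axis) of the 10 genes with the largest rise and the 10 with the largest fall by the rule for naming genes, which leaves out names of the Gm, Rik, pseudogene or accession type, one point per library, with a bar at the mean of the 3 libraries of a genotype. The genotypes do not overlap for any of these genes, which the rule required, and Ly6c2 goes from a WT mean of 30.2 to 205 CPM.

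Genes that mark M1 activation mostly rose. Of the 23 tested M1-associated cytokines and effectors, 17 rose and 2 fell (17 and 3 adjusted over the list alone; camera adjusted p = 8.87e-05, and adjusted p = 0.225 with an estimated correlation). Il12b, a subunit of IL-12 and IL-23, rose 1.60-fold (adjusted p = 1.24e-04), Il12a 2.67-fold, Il27 2.14-fold and the co-stimulatory ligand Cd86 1.31-fold. Nos2, the inducible nitric oxide synthase, was among the most abundant transcripts and rose 1.16-fold (6053 ± 165 CPM in WT and 7044 ± 317 CPM in Cd226-/- (SD, n = 3); adjusted p = 0.00328). Il6 fell (log2 fold change -0.49 ± 0.096 (SE), adjusted p = 8.47e-04), and Il1b did not pass (log2 fold change 0.098, adjusted p = 0.211). Tnf was listed at 0 in all 6 libraries, in a run of 25 neighbouring protein-coding genes at 0 that also holds broadly used genes, and gives no information on its expression. The M2-type gene Arg1 fell (log2 fold change -0.48 ± 0.062 (SE); 4160 ± 189 CPM in WT and 2987 ± 283 CPM in Cd226-/- (SD, n = 3)), while Il10 did not pass (log2 fold change 0.023, adjusted p = 0.957). Mrc1 did not pass either (log2 fold change 0.49, adjusted p = 0.597): its counts were 102, 114 and 102 in WT and 76, 80 and 266 in Cd226-/-, and without Cd226-/- replicate 3 the value was -0.31. Among 23 M2-associated genes, 6 rose and 6 fell (the same numbers adjusted over the list alone), and the list was not called (camera adjusted p = 0.969, and adjusted p = 0.982 with an estimated correlation).

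**Figure D2:**
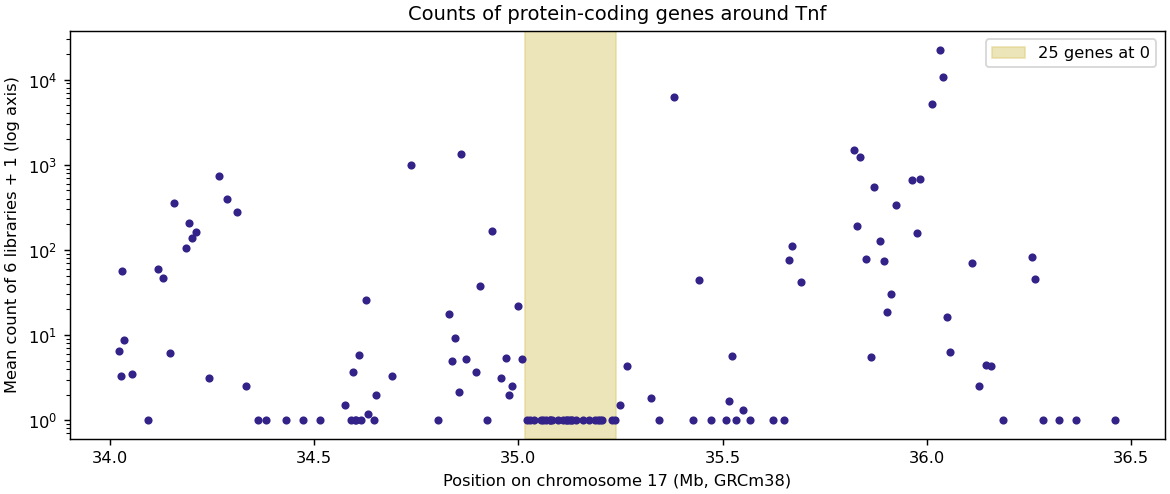
Mean count over the 6 libraries plus 1 (log axis) of protein-coding genes by position on chromosome 17 (Mb, GRCm38), one point per gene. The shaded run from 35016360 to 35238767 holds 25 consecutive genes at 0, Tnf among them.

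Interferon-stimulated genes were higher as a list: of 34 tested, 12 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 0.00659, and adjusted p = 0.532 with an estimated correlation). Isg20 rose 2.16-fold, Isg15 1.60-fold and Bst2 1.36-fold. The interferon-gamma GTPases were not called; of 19, 2 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.487, and adjusted p = 0.918 with an estimated correlation). In the MHC class I list, 17 genes were tested: 7 rose and 0 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.00446, and adjusted p = 0.174 with an estimated correlation). Of these, 11 lie in a wider part of chromosome 17 around the run of genes at 0, and whether they lost reads was not tested. Low counts were not confined to the run: its neighbours Vars and Ddx39b had 25 and 3 counts over all 6 libraries. Of list members in that part, H2-D1 had a mean of 3.33 counts and H2-Q6 0, against 22398 for H2-T23. Of the 6 tested genes outside that part 5 rose, such as Psme1 (1.27-fold) and the class I transactivator Nlrc5 (1.21-fold). For MHC class II, 8 genes were tested: 4 rose and 0 fell (the same numbers adjusted over the list alone), without a list call (camera adjusted p = 0.180, and adjusted p = 0.393 with an estimated correlation); 5 of them lie in the same region, and without Cd226-/- replicate 1 the list was called (adjusted p = 0.00103), as it was by limma-voom (0.0358) and fry (0.0149). Over all alternatives the adjusted p of the class II list ranged from 0.00103 to 0.393. The number of its 8 tested genes that rose was 1 when scaled by library size, 2 with the replicate number as a block and 4 by limma-voom. H2-Aa had 204, 167 and 310 counts in WT and 234, 754 and 698 in Cd226-/-.

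In the list named NF-kB feedback inhibitors and subunits, of 20 tested 9 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.00764, and adjusted p = 0.393 with an estimated correlation). The list members Tnfaip3 and Socs3 rose 1.38-fold and 1.39-fold, and the RNase gene Zc3h12a fell (log2 fold change -0.37 ± 0.052 (SE)). Immediate early genes rose in 12 of 21 cases with none falling, also adjusted over the list alone (camera adjusted p = 2.44e-04, and adjusted p = 0.371 with an estimated correlation), as in Atf3 (1.40-fold) and Klf2 (1.86-fold). The chemokine list split: of 20, 6 rose and 5 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.361, and adjusted p = 0.538 with an estimated correlation). Its median and mean log2 fold changes were 0.13 and 0.040 while the list test pointed lower, with Cxcl1 falling by 1.27 on the log2 scale and Ccl5 rising 1.52-fold. Toll-like receptor signalling genes split too: of 26 tested 8 rose and 7 fell (8 and 8 adjusted over the list alone; camera adjusted p = 0.685, and adjusted p = 0.835 with an estimated correlation; median 0.064, mean -0.00103). The receptors Tlr4, Tlr8 and Tlr13 fell, with log2 fold changes of -0.55, -0.68 and -0.65. Of 17 inflammasome genes, 5 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.344, and adjusted p = 0.792 with an estimated correlation), among them Mefv (1.55-fold) and Il18 (1.63-fold). Complement genes were called higher: of 15 tested 5 rose and 3 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.00748, and adjusted p = 0.174 with an estimated correlation). C3 rose 1.79-fold and Serping1 2.17-fold. The list members C4b and Cfb lie in the wider part of chromosome 17 around the genes at 0, where loss of reads was not tested.

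Several lists of metabolic and stress genes were called. Oxidative stress response genes, many of them targets of the regulator NRF2, fell: of 21 tested, 3 rose and 16 fell (the same numbers adjusted over the list alone; camera adjusted p = 3.36e-18, and adjusted p = 0.174 with an estimated correlation). Gclm, of glutathione synthesis, had log2 fold change -0.83 ± 0.057 (SE), Hmox1, the heme oxygenase, -0.87, Txnrd1, the thioredoxin reductase, -0.67 and the metallothionein Mt2 -0.87; Prdx5 and Sod2 rose 1.33-fold and 1.18-fold. Of 21 glycolysis genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 1.11e-10, and adjusted p = 0.174 with an estimated correlation). Pfkp and Pfkl, phosphofructokinase subunits, rose 1.85-fold and 1.62-fold, and the glucose transporter Slc2a1 1.65-fold. Hypoxia response genes were higher: of 20 tested 15 rose and 2 fell (the same numbers adjusted over the list alone; camera adjusted p = 1.90e-09, and adjusted p = 0.174 with an estimated correlation), Bnip3 rising 2.37-fold and the oxygen sensor Egln1 1.87-fold. In the unfolded protein and heat shock list, of 19 tested 13 rose and 1 fell (the same numbers adjusted over the list alone; camera adjusted p = 2.69e-10, and adjusted p = 0.174 with an estimated correlation). Asns and the pseudokinase gene Trib3, both known targets of the amino acid response factor ATF4, rose 4.30-fold and 3.21-fold, whereas the heat shock gene Hsph1 fell (log2 fold change -0.62 ± 0.054 (SE)). Fatty acid oxidation genes were lower: of 16 tested 1 rose and 8 fell (1 and 9 adjusted over the list alone; camera adjusted p = 0.00456, and adjusted p = 0.174 with an estimated correlation): Slc25a20 and Etfdh had log2 fold changes of -0.53 and -0.47.

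Cytosolic ribosomal protein genes were called higher: of 45 tested 32 rose and 1 fell (34 and 1 adjusted over the list alone; camera adjusted p = 1.60e-12, and adjusted p = 0.297 with an estimated correlation), as in Rps20 (1.68-fold) and Rpl3 (1.80-fold); many have processed pseudogenes, so their counts are uncertain. Of 11 mitochondrially encoded transcripts, 6 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 8.87e-05, and adjusted p = 0.393 with an estimated correlation). ND1 rose 1.82-fold and CYTB 1.24-fold, whereas COX3, with 83, 96 and 147 counts in WT and 122, 290 and 362 in Cd226-/-, did not pass (adjusted p = 0.108). Nuclear oxidative phosphorylation genes were not called: of 36 tested 10 rose and 0 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.0868, and adjusted p = 0.584 with an estimated correlation). They were called by limma-voom (adjusted p = 0.0340) and fry (0.0184), over a range of 0.0184 to 0.850 for all alternatives. Uncalled too were the tricarboxylic acid cycle (2 higher and 5 lower of 20, camera adjusted p = 0.123, and adjusted p = 0.600 with an estimated correlation; Idh1 fell by 0.84 on the log2 scale), cholesterol biosynthesis (3 and 1 of 23, 0.837, and adjusted p = 0.850 with an estimated correlation) and fatty acid synthesis (2 and 4 of 14, 0.645, and adjusted p = 0.751 with an estimated correlation), and the same numbers held adjusted over the list alone. The tricarboxylic acid cycle list was called without a filter (adjusted p = 0.0314) and by fry (0.0278; range over all alternatives 0.0278 to 0.600), and fatty acid synthesis by fry (0.0125). The desaturase genes Scd1 and Scd2 nevertheless rose 2.07-fold and 2.29-fold. Lipid uptake, storage and efflux genes divided evenly: of 27 tested 11 rose and 11 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.969, and adjusted p = 0.982 with an estimated correlation). The median and mean were 0.020 and 0.066 while camera pointed lower. Apoe rose 2.15-fold to 2078 ± 18.4 CPM and Lpl 1.61-fold, while the scavenger receptor Cd36 fell (log2 fold change -1.03 ± 0.056 (SE)).

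The S and G2/M cell cycle list was at the threshold: of 34 tested 8 rose and 0 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.0488, and adjusted p = 0.463 with an estimated correlation). Ccne1, cyclin E1, rose 2.61-fold and Top2a 2.05-fold. The list missed the threshold without WT replicate 2 (adjusted p = 0.0737), WT replicate 3 (0.108) or Cd226-/- replicate 3 (0.148), and with replicate 1 as the only Cd226-/- library (0.309), where the adjusted p of Top2a was 0.597. It also missed with DESeq2 size factors (0.0515) and at a mean of 5 CPM (0.213), and its adjusted p ranged from 0.00699 to 0.463 over all alternatives. Replication-dependent histone genes were lower, 3 of 5 tested (4 adjusted over the list alone; camera adjusted p = 0.00446, and adjusted p = 0.297 with an estimated correlation). The list was not called without a filter on low counts (adjusted p = 0.0578; range over all alternatives 2.42e-04 to 0.297). Hist1h1c had log2 fold change -0.90 ± 0.13 (SE). Matrix remodelling genes were called lower: of 23 tested 7 rose and 12 fell (7 and 13 adjusted over the list alone; camera adjusted p = 0.0254, and adjusted p = 0.458 with an estimated correlation). The call was lost without WT replicate 1 (adjusted p = 0.0779) or Cd226-/- replicate 2 (0.0531), and over all alternatives the adjusted p ranged from 0.00234 to 0.458. It was also lost with replicate 1 as the only Cd226-/- library. There the mean log2 fold change was -2.4e-04, against -0.042 in the main fit. Timp3 and Tgfbi fell by 1.38 and 0.79 on the log2 scale, and Timp1 rose 1.55-fold.

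Genes near Cd226 on chromosome 18 were lower: of 19 tested, 1 rose and 6 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.0112, and adjusted p = 0.174 with an estimated correlation). Cyb5a (84851338 to 84879871) and Cndp2 (84667465 to 84685702) had log2 fold changes of -0.64 and -0.43. Cd226 itself lies at 89176954 to 89272232, and whether the falls depend on the distance from it was not tested. The median log2 fold change of the list was -0.095, and 30.9% of all tested genes changed. Of the 8 tested members of the CD226 receptor family and its ligands, 1 fell and none rose, and 0 passed adjusted over the list alone (camera adjusted p = 0.642, and adjusted p = 0.807 with an estimated correlation). Phagocytosis and Fc receptor genes split: of 28 tested 11 rose and 8 fell (11 and 9 adjusted over the list alone; camera adjusted p = 0.228, and adjusted p = 0.463 with an estimated correlation; median -0.00515, mean 0.061): the receptor tyrosine kinase Axl rose 3.10-fold (42.2 ± 1.87 CPM in WT and 131 ± 9.33 CPM in Cd226-/- (SD, n = 3)) and Fcgr3 fell (log2 fold change -0.49 ± 0.056 (SE)). For adhesion and migration, of 27 tested 11 rose and 9 fell (12 and 11 adjusted over the list alone; camera adjusted p = 0.337, and adjusted p = 0.460 with an estimated correlation). For apoptosis and survival, of 27 tested 7 rose and 6 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.952, and adjusted p = 0.982 with an estimated correlation), and Bid fell by 0.76 on the log2 scale, from 42.0 to 24.9 CPM. For the lysosome, of 34 tested 11 rose and 6 fell (11 and 7 adjusted over the list alone; camera adjusted p = 0.337, and adjusted p = 0.850 with an estimated correlation).

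Markers of other cell types also moved. B and plasma cell markers were called higher: of 11 tested 9 rose and 1 fell (the same numbers adjusted over the list alone; camera adjusted p = 2.13e-06, and adjusted p = 0.292 with an estimated correlation), at low levels: Cd22 went from 5.11 ± 0.244 to 11.8 ± 1.12 CPM (SD, n = 3). Monocyte markers were called higher: of 14 tested 7 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 1.16e-07, and adjusted p = 0.170 with an estimated correlation). Ccr2 rose 2.12-fold and Plac8 1.95-fold. Dendritic cell markers were called higher: of 15 tested 10 rose and 1 fell (the same numbers adjusted over the list alone; camera adjusted p = 1.29e-04, and adjusted p = 0.174 with an estimated correlation). Fscn1 rose 1.84-fold. Fibroblast and stromal markers were called higher: of 18 tested 9 rose and 2 fell (the same numbers adjusted over the list alone; camera adjusted p = 8.87e-05, and adjusted p = 0.336 with an estimated correlation). Bgn rose 2.20-fold and Col1a2 1.86-fold. Neutrophil markers were called higher, although only 8 of the 19 list members had enough counts to be tested. Of these 8, 2 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0221, and adjusted p = 0.293 with an estimated correlation). Csf3r rose 1.60-fold and Lcn2 2.87-fold, and which cells these transcripts came from was not tested. The call was lost without WT replicate 1 (adjusted p = 0.0529) or Cd226-/- replicate 3 (0.0541). It was also lost by limma-voom (0.0641), with the GC and length offsets chosen after seeing the data (0.0635) and without a filter (0.127, mean log2 fold change -0.0086), over a range of 1.57e-05 to 0.293 for all alternatives. Osteoclast markers missed the threshold (of 10 tested 5 rose and 1 fell (7 and 1 adjusted over the list alone); camera adjusted p = 0.0675, and adjusted p = 0.458 with an estimated correlation) and passed it without WT replicate 1 (adjusted p = 0.0478), WT replicate 2 (0.0163) or Cd226-/- replicate 2 (0.0436). They also passed it by limma-voom (0.0358), without a filter (0.0187), by fry (0.0176) and with replicate 1 alone (0.0437), over a range of 0.0163 to 0.458 for all alternatives. Macrophage identity genes were not called (of 17 tested 6 rose and 6 fell (7 and 6 adjusted over the list alone); camera adjusted p = 0.969, and adjusted p = 0.982 with an estimated correlation), and fry pointed higher while camera, the median and the mean pointed lower. Irf8 rose 1.55-fold and Cebpa fell (log2 fold change -0.66 ± 0.071 (SE)). Among further cell types, lists of T and natural killer cells (0 of 13 past the threshold; camera adjusted p = 0.721, and adjusted p = 0.835 with an estimated correlation), mast cells, basophils and eosinophils (3 higher and 3 lower of 10; 0.969, and adjusted p = 0.982 with an estimated correlation), endothelial cells and adipocytes (2 and 2 of 6; 0.923, and adjusted p = 0.952 with an estimated correlation) and megakaryocytes and platelets (1 and 0 of 6; 0.746, and adjusted p = 0.835 with an estimated correlation) were not called, with the same counts adjusted over the list alone. For mast cells camera pointed lower while the median (0.031) and mean were positive, and for megakaryocytes the median was -0.031 and the mean 0.037. Erythroid markers (1 higher and 1 lower of 2 tested) and sex-linked genes (1 higher of 4) were too few for the list test.

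**Figure D3:**
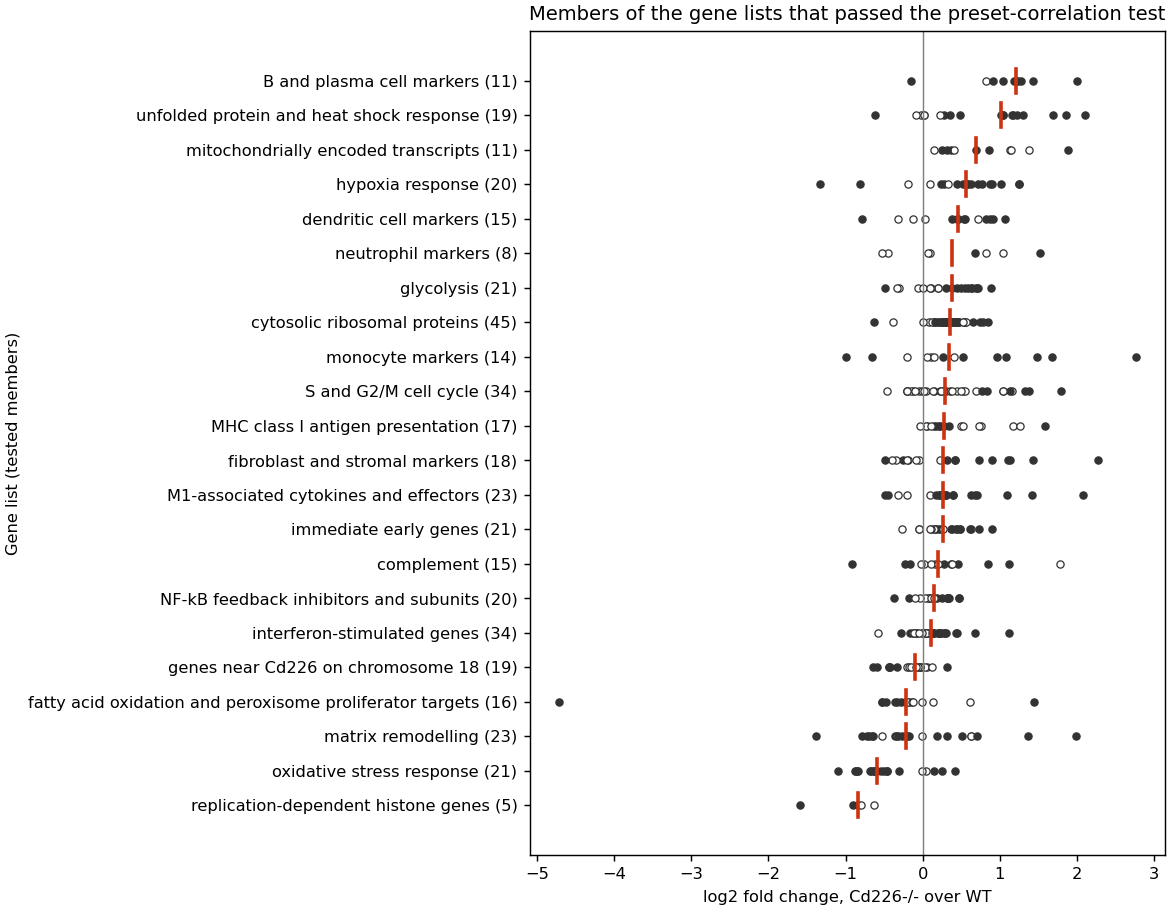
Log2 fold change (Cd226-/- over WT) of each tested member of the 22 gene lists called with a preset correlation of 0.01, filled where the gene had an adjusted p under 0.05, with a red bar at the list's median. Lists run from histone genes (median -0.84) to B and plasma cell markers (median 1.21), and no list was called with an estimated correlation.

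Of the 44 lists tested, 22 were called with the preset correlation, 17 higher and 5 lower in Cd226-/-. With an estimated correlation 0 were called by camera (the called lists had adjusted p from 0.170 to 0.532), 10 of the 44 had an unadjusted p under 0.05, and fry, which asks whether a list's genes move one way on balance, called 30. Beyond the 22, fry called MHC class II, nuclear oxidative phosphorylation, the tricarboxylic acid cycle, fatty acid synthesis, phagocytosis, adhesion, osteoclasts and megakaryocytes.

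A pair of the Cd226-/- libraries held transcripts with few or no counts in the rest. Albumin (Alb) had 266 and 279 counts in Cd226-/- replicates 2 and 3 and 0 in the other 4 libraries. Xist had 64 and 156 counts in the same libraries and 0 elsewhere, although the Y-linked gene Ddx3y was abundant in all 6 (1465 to 1982 counts). Summed over 34 liver transcripts, a list written after the counts were seen, these libraries had 755 and 934 counts, or 0.00446% and 0.00506% of their totals, against 3 to 7 in the others.

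**Figure D4:**
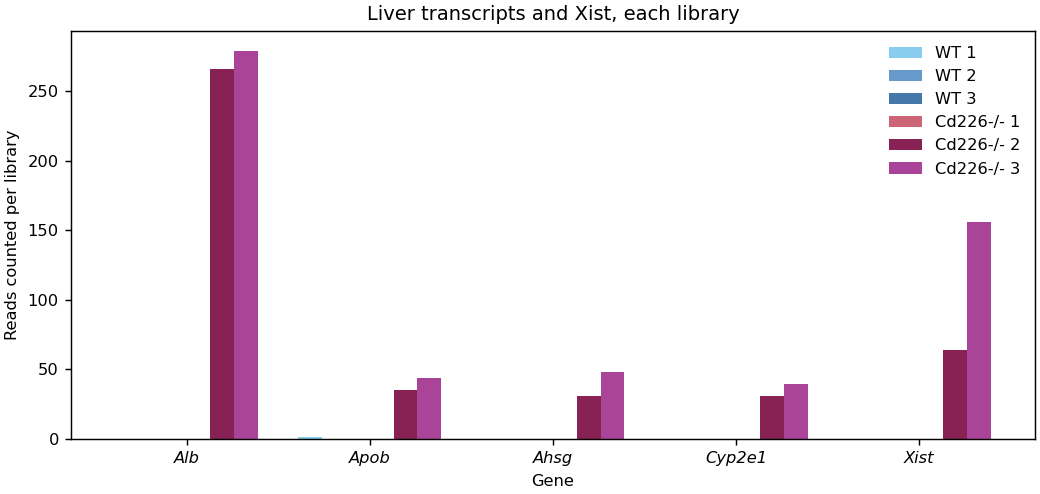
Reads counted per library for 4 liver transcripts and Xist (bars from 0). Cd226-/- replicates 2 and 3 hold 266 and 279 counts of Alb, and the other 4 libraries hold 0.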

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

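Of the tests here, those on offsets, on replicate 1 alone, on the share of liver reads, on expression by the knockout cells, on the shared source of Xist and on the genes at 0 were chosen after the result was seen. Groups of 3 libraries are too small for a test of single outlying samples.

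Transcripts outside the tested genes stood above the WT level in a pair of Cd226-/- libraries: Alb with 266 counts in replicate 2 and 279 in replicate 3, and Xist with 64 and 156, against 0 in WT.

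For the liver transcripts, expression by Cd226-/- macrophages stays open. On a second set of 42 hepatocyte genes, chosen without looking at their counts, the upper 95% limit in replicate 1 was 4.27 summed CPM. This exceeds the bound of 1/3 of the level in replicates 2 and 3 and comes from 1 library. A library at the WT level could hardly meet that bound: WT libraries held 3.09 to 3.95 CPM (upper limits 4.05 to 4.99). Replicate 1 was at that level with 3.34 CPM, so the test cannot decide. Of the 34 liver transcripts replicate 1 held 0.318 CPM, against 44.6 and 50.6 in replicates 2 and 3, again from 1 library. Liver RNA or reads from a liver library is a candidate source. Of the 42 genes of the second set, 90.5% had a count in replicates 2 and 3 together. By library, 37 had a count in replicate 2 and 34 in replicate 3, against 9 in replicate 1 and 11 to 14 in each WT library. The test fixed beforehand nevertheless missed its bound of 3: the summed count was 2.49 times that of the highest other library (207 against 83, in WT replicate 3). The explanation is left open because the 95% interval, 1.92 to 3.26, includes 3, a reading adopted after the value was seen; the rule as first written would have excluded it. A single source of fixed composition for Xist and the liver transcripts is argued against by 8.48 Xist counts per 100 liver counts in replicate 2 and 16.7 in replicate 3 (Fisher's exact test, two-sided, p = 9.07e-06, counting error only), while the 33 liver transcripts with at least 10 counts spread between these libraries about as counting error does (chi-square 33.3, permutation p = 0.406).

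The number of changed genes, 4086, is argued not to come from a GC or length trend as the whole cause, since 4007 genes were called with per-library offsets, 3608 of them among the 4086. Liver RNA as the whole cause is argued against, since dilution would need a median of 24.5% of reads to lower the genes called lower, and the 34 liver transcripts held at most 0.00540% (upper 95% limit), on the assumption, not measured here, that they make up at least 1 in 100 of liver RNA. Other foreign RNA in replicates 2 and 3 stays open: 2957 genes were called with replicate 1 as the only Cd226-/- library, 2503 of them among the 4086, but this rests on 1 library, with the spread taken from WT alone. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05: the real split, 1 of the 10, gave 4086 genes (highest other 0) and 22 lists (highest other 15, so lists were called also where the genotypes were mixed). Litter, culture and sequencing day are not in the labels. Such a difference, or another between the WT and Cd226-/- animals, stays open as untested beside an effect of the genotype. Cd226 itself had a mean of 0.769 CPM in WT and 0.547 CPM in Cd226-/-, so its counts do not tie the 4086 changes to its loss.

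Tnf was listed at 0 in macrophages given LPS, inside an unbroken run of 25 protein-coding genes at 0 in all 6 libraries (chromosome 17, 35016360 to 35238767, from Vwa7 to Atp6v1g2). A lack of transcription is argued against, because Csnk2b, Bag6, Clic1, Abhd16a, Prrc2a and Gpank1, used by cells of every kind, summed to 0 counts there. Loss of the reads in alignment or counting is a candidate explanation, and the run of 25 was itself what drew attention, so it cannot count as a test. An aligned index with extra copies of the region might produce such a loss; the index was not analysed here.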

How the results depend on the processing

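The fit with replicate 1 as the only Cd226-/- library and the GC and length offsets were chosen after seeing the data; the other alternatives were fixed before the data were examined. The count of 4086 changed genes stayed within 1.5 times under other scalings, filters and tools (3339 to 4537) and with each library left out (3263 to 4379), and every one of the 4086 that these fits tested kept its direction. With replicate 1 alone 4078 did, and with the offsets 4074. The count moved by construction with stricter thresholds, to 571 (403 higher, 168 lower) with a 2-fold minimum and to 2636 (1167 lower) at an adjusted p under 0.01. Scaling by total count gave 1773 higher and 2764 lower. With replicate 1 alone the lysosome list passed (adjusted p = 0.0112), with the spread from WT only, and in none of the other 14 settings with a preset correlation or fry; with all 6 libraries it had adjusted p = 0.850 with an estimated correlation. Cd226 stayed short of the threshold in every fit that tested it and was not tested at a mean of 5 CPM. The 22 called lists became 0 with an estimated correlation and 20 to 30 under the other alternatives. Of the 22, 18 were called in all of those others. A correlation above the preset 0.01 cannot be the whole reason for the 0. Its estimate was -0.042 for monocyte markers, -0.038 for complement and -0.022 for dendritic cell markers, against 0.66 for mitochondrially encoded transcripts. The planted list of independently simulated genes had camera adjusted p = 2.74e-72 with the preset correlation and 0.0185 with the estimated one. Other reasons were not tested. The replicate number as a block gave 4137 genes (2185 higher, 1952 lower) and 22 lists; deviations of same-numbered libraries correlated at 0.011, -0.013 and 0.015, so the numbers do not pair the samples, although 4 of 6 libraries correlated best with their own number.

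No named gene or list past its threshold reversed. Among those short of it, the log2 fold change of 2 genes and the direction of the test of 11 lists reversed (values are mean log2 fold changes); the cause was not tested. Il10 was -0.031 by library size, -0.019 by limma-voom, -0.0021 with the block, and from -0.13 to 0.25 with a library left out. Mrc1 was -0.41 with replicate 1 alone, and ranged from -0.31 to 0.80 with a library left out. M2-associated genes had 0.26 by library size, 0.17 without a filter, 0.20 at a mean of 5 CPM, from 0.17 to 0.38 with a library left out. Apoptosis and survival had 0.0016 by library size, from 0.037 to 0.065 with a library left out. Chemokines had 0.031 by limma-voom. Cholesterol biosynthesis had -0.013 with replicate 1 alone. Endothelial and adipocyte markers had -0.11 with replicate 1 alone, from -0.065 to 0.038 with a library left out. Fatty acid synthesis had 0.14 by limma-voom. Interferon-gamma GTPases had from 0.023 to 0.17 with a library left out. Lipid uptake, storage and efflux had 0.066 by fry, 0.15 with replicate 1 alone, 0.074 with the offsets, from 0.020 to 0.094 with a library left out. Macrophage identity had -0.043 at a mean of 5 CPM, -0.030 by limma-voom, -0.055 by fry, -0.039 with replicate 1 alone, from -0.080 to 0.022 with a library left out. Mast cell, basophil and eosinophil markers had 0.092 by library size, 0.12 by limma-voom, 0.15 by fry, from 0.084 to 0.26 with a library left out. Toll-like receptor signalling had 5.06e-04 by limma-voom. Depth limits genes of few counts, such as Cd226 itself.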

Other observations

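The lists and genes in this part were chosen after their values were seen, so their p-values do not test them independently. Genes of amino acid and one-carbon synthesis and transport rose in 13 and fell in 5 of 27 cases: the serine synthesis genes Phgdh and Psat1 rose 2.93-fold and 2.87-fold, the mitochondrial folate gene Mthfd2 2.78-fold, the proline synthesis gene Aldh18a1 3.02-fold and the amino acid transporter Slc7a5 2.73-fold. Glul, the glutamine synthetase, fell (log2 fold change -0.61 ± 0.051 (SE)). This list had camera p = 8.70e-06, and p = 0.0371 with an estimated correlation. Of 20 aminoacyl-tRNA synthetase genes 9 rose and 2 fell, Cars by 1.66-fold and Aars by 1.59-fold (camera p = 0.00466, and p = 0.0918 with an estimated correlation). Alpha and beta tubulin genes rose in 9 of 11 cases with none falling, Tubb5 by 2.29-fold and Tuba1a by 2.22-fold (camera p = 1.40e-20, and p = 0.00789 with an estimated correlation), and near-identical copies make single members uncertain. Tubb5 lies in the wider part of chromosome 17 around the genes at 0, where loss of reads was not tested.

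In the Ly6 family on chromosome 15, 6 of 7 tested genes rose and none fell, Ly6i by 2.17-fold beside Ly6c2 (camera p = 5.26e-21, and p = 0.00116 with an estimated correlation). In the Ms4a family 7 rose and 1 fell of 11: Ms4a4c rose 3.57-fold and Ms4a14 fell (log2 fold change -1.29 ± 0.16 (SE)), with camera p = 3.44e-07, and p = 0.0276 with an estimated correlation. Mid1, G530011O06Rik and Erdr1, at the end of chromosome X (from 169685199), rose 5.69-fold, 8.46-fold and 4.90-fold. Wdfy1, an adaptor in toll-like receptor signalling, rose 3.40-fold, and the nuclear long non-coding RNA Neat1 2.36-fold. LOC630751 had 0 counts in the 3 WT libraries and 304, 308 and 286 in Cd226-/- replicates 1 to 3, at least 324-fold higher against a floor of 3 counts over the WT group. Gm30783 had 0 counts in WT and 43, 93 and 77 in Cd226-/-, at least 77.5-fold higher on the same floor.

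Some single genes stood apart in 1 library: Cd163 had 129 counts in Cd226-/- replicate 3 and 9 to 17 in the other 5 libraries, Adgre4 113 against 10 to 31, and Cbr2 101 against 4 to 27. Laptm5 had 2121 counts in WT replicate 3 and 221 to 549 elsewhere.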
